A study of Homo sapiens with 120 samples.

How the data were processed

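RNA from 5 lung cancer cell lines was sequenced after 48 h of treatment, in 120 libraries. Per the labels' protocols, libraries were made with a TruSeq v2 kit and read as single ends of 50 bp on a HiSeq2500. The deposited values are raw counts per Ensembl gene for 58302 genes in 4 tables. Per the submitters' processing notes, the authors aligned reads with GSNAP 2013-10-10 to GRCh38 and tested with DESeq2 and limma. The program that counted reads, its annotation and its strand setting are not given in the labels or notes used here, so values of overlapping genes, antisense genes and close paralogs are uncertain. Symbols were found for 57532 gene IDs, and 58039 IDs occur in GENCODE release 29, from which the positions printed here were taken.

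Treatments were DMSO (0.02%), G03498025 at 1 µM, the partner compound at 1 µM, and both; single treatments held 0.01% DMSO. Each cell line was fitted separately. Library sets were defined before the data were examined as stretches of libraries, in order of library number, in which each treatment and replicate number occurs once. The labels do not name them. Total counts ran from 18.7 M to 87.3 M per library, with a median of 33.2 M.

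Genes were filtered with filterByExpr and scaled with TMM in edgeR 4.0.16 (R 4.3.3, limma 3.58.1). All 4 treatments of a line shared 1 quasi-likelihood fit, with the library set as an additive term where a line had several. Contrasts were G03498025 against DMSO, the partner against DMSO, the combination against each single compound, and the interaction. Adjusted p values are Benjamini-Hochberg values, called under 0.05. F tests asked whether treatment effects differ between the sets of a line or between lines.

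Before the data were examined, 25 gene lists with 426 entries were fixed. They cover YAP/TAZ-TEAD targets, Hippo components, MAPK output, AP-1 and immediate early genes, G1/S and G2/M genes, CDK inhibitors and p53 targets, the BCL2 family, interferon-stimulated genes and antigen presentation. They also cover mesenchymal, epithelial, alveolar type 2, gastric and mucinous, and squamous genes, receptor tyrosine kinases and ligands, SRF/MRTF cytoskeletal targets, cholesterol synthesis, ATF4 stress genes, NRF2 targets and glycolysis. Fibroblast, leukocyte and endothelial, mitochondrial and ribosomal lists served as controls. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a contrast. A gene is said to have risen or fallen where it passed over all genes; counts adjusted over the list alone are given beside these.

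Genes are named if they belong to a fixed list. Otherwise, for each line and contrast, the 5 largest rises and 5 largest falls are named among genes past the threshold with a mean of at least 3 log2 CPM (prior count 0.5) and no overlap between the compared groups in any library set. The overlap condition was not used for the interaction. Other genes are marked as chosen after their values were seen.

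The fit was tested on simulated data drawn from the real means and library sizes, with 200 genes changed. For G03498025 against DMSO in NCI-H358 (18277 genes), 35.8% of genes changed by a log2 of 0.5, 74.6% changed by 1 and 89.4% changed by 2 were recovered, with 3 false calls. In NCI-H2122 (17733 genes) these shares were 50.7%, 92.5% and 98.5%, with 13 false calls. In NCI-H2030 X1.1 (17673 genes) they were 49.3%, 76.1% and 95.5%, with 6 false calls. In NCI-H2228 (18554 genes) they were 62.7%, 94.0% and 98.5%, with 7 false calls. In SNU-2292 (18904 genes) they were 61.2%, 83.6% and 97.0%, with 8 false calls. The simulated noise was independent between libraries, and each change was the same in every library set. In the lines with several sets the real treatment effects differed between sets. These shares and false calls therefore cannot vouch for the pooled fits of NCI-H358, NCI-H2228 and SNU-2292.

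Alternatives were DESeq2 1.42.0, its size factors, no low-count filter, a replicate block, fits of the 2 groups alone, no library set term, each set alone, each library left out in the lines with 1 set, fry, and an estimated correlation. After the data were seen, fits without 2 doubted libraries of NCI-H2228 set 2 and an average of treatment-by-set means were added. No library was left out of the reported fits.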

Results

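RNA was sequenced from 5 human lung cancer cell lines after 48 h with DMSO, with 1 of 2 inhibitors at 1 µM, or with both together, giving 120 libraries in 20 groups. The labels name the compounds by code. G03498025 was given to every line. Its partner was G03427947 in NCI-H358, NCI-H2122 and NCI-H2030 X1.1, and G02925614 in NCI-H2228 and SNU-2292. The labels do not say which code is the pan-TEAD inhibitor. Each group held 6 libraries in NCI-H358, 3 in NCI-H2122 and in NCI-H2030 X1.1, and 9 in NCI-H2228 and in SNU-2292. In order of library number, the libraries were divided where the labels repeat into 10 stretches of 12, called library sets here. In each set every treatment and replicate number occurred once. The numbers themselves show no break between the sets of NCI-H2228 or of SNU-2292. NCI-H358 had 2 such sets, NCI-H2122 and NCI-H2030 X1.1 had 1 each, and NCI-H2228 and SNU-2292 had 3 each. The labels do not say what the sets are or whether the replicates were separate cultures. The total count per library ran from 18.7 M to 87.3 M counts, with a median of 33.2 M.

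Comparing G03498025 with DMSO asks what this compound changed by itself. It lowered YAP/TAZ-TEAD target genes in every line. CCN1 and CCN2 fell in all 5 lines, ANKRD1 fell in the 3 lines in which it was measured, and no gene of the 22-gene YAP/TAZ-TEAD list rose in any line. AMOTL2 fell in 4 lines and AXL in 4. The fold changes are log2 values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CCN1 (ENSG00000142871, chromosome 1, 85580761 to 85583962, GRCh38) fell by 1.21 ± 0.22 (SE, adjusted p = 0.00295) in NCI-H358, by 1.26 ± 0.11 (5.1e-07) in NCI-H2122 and by 1.40 ± 0.06 (8.7e-12) in NCI-H2030 X1.1. It fell by 0.83 ± 0.19 (adjusted p = 0.00346) in NCI-H2228 and by 1.16 ± 0.24 (8.8e-04) in SNU-2292. CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373) fell by 1.07, 1.80, 2.14, 1.16 and 0.92 in these lines in the same order. ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276) fell by 2.81 in NCI-H358, by 1.18 in NCI-H2228 and by 3.14 in SNU-2292. In NCI-H2030 X1.1, CCN1 stood at 441.2 ± 19.4 counts per 1 M counts (CPM) in DMSO (mean ± SD, n = 3) and at 167.3 ± 6.06 with G03498025.

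**Figure D1:**
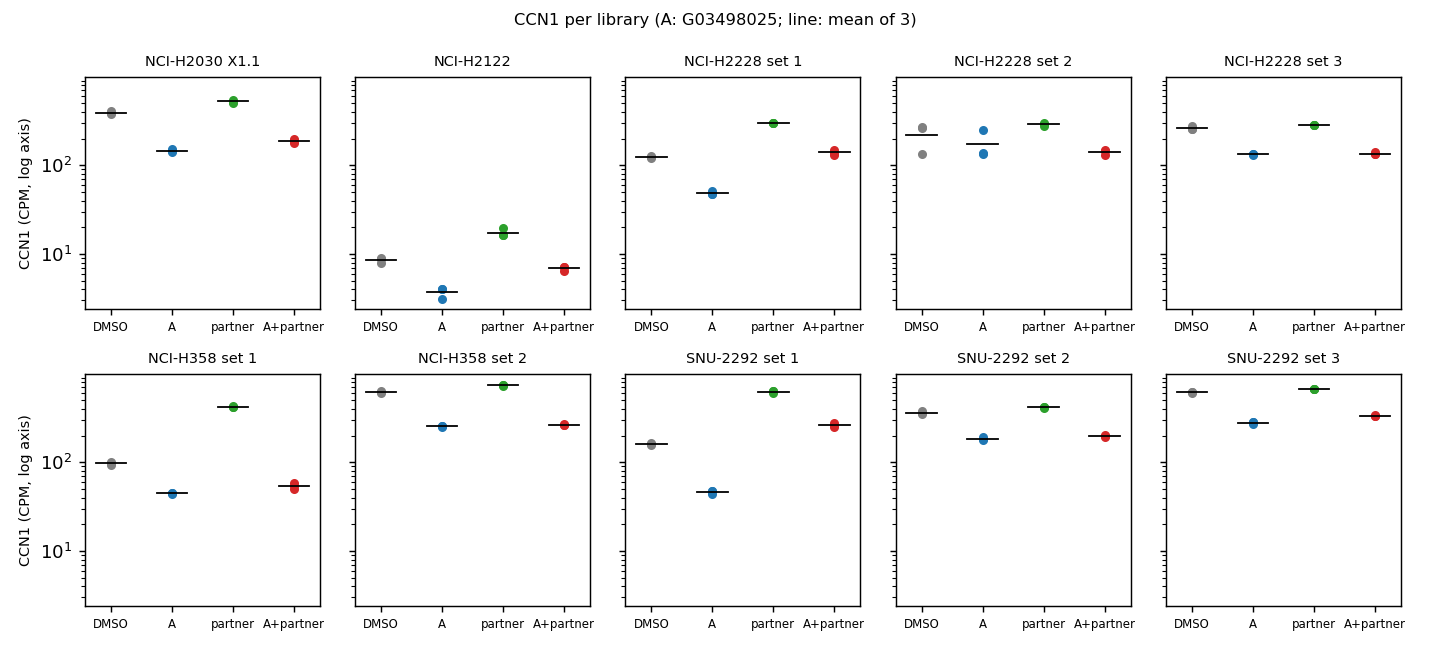
CCN1 in CPM on a log axis, 1 point per library and a line at the mean of 3 libraries, for each treatment (A is G03498025) in each of the 10 library sets. Plotted CPM were scaled over all libraries of the series, so they differ from the CPM in the text, scaled within a line. In NCI-H2030 X1.1 the points ran from 374.5 to 407.2 in DMSO and from 141.3 to 154.2 with G03498025. In NCI-H2228 set 2 the points labelled DMSO and G03498025 overlap.

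As a list, the YAP/TAZ-TEAD targets fell in all 5 lines by camera with a preset correlation. In NCI-H358 their mean was -0.59 (6 fell, 15 did not pass, and 11 fell when adjusted over the list alone; adjusted p = 9.8e-17). The mean was -0.63 in NCI-H2122 (12 fell and 8 did not pass; 16 fell adjusted over the list alone; 5.4e-32) and -0.56 in NCI-H2030 X1.1 (16 fell and 5 did not pass; 17 adjusted over the list alone; 4.0e-38). In NCI-H2228 it was -0.38, with 13 fallen, 9 not passed and 18 fallen adjusted over the list alone (1.7e-16). In SNU-2292 it was -0.53, with 11 fallen, 11 not passed and 16 fallen adjusted over the list alone (4.8e-12). With an estimated correlation 4 of these calls held, at adjusted p of 0.00173, 0.00261, 0.00141 and 0.0312, and the SNU-2292 call was lost (0.0799). Fitted alone, sets 1, 2 and 3 of SNU-2292 each held the call. Fitted within single library sets, the list mean lay between -0.45 and -0.63 in 10 of 10 sets once 2 doubted libraries of NCI-H2228 set 2, described at the end, were left out. As labelled, that set gave -0.15 with 0 genes passing.

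**Figure D2:**
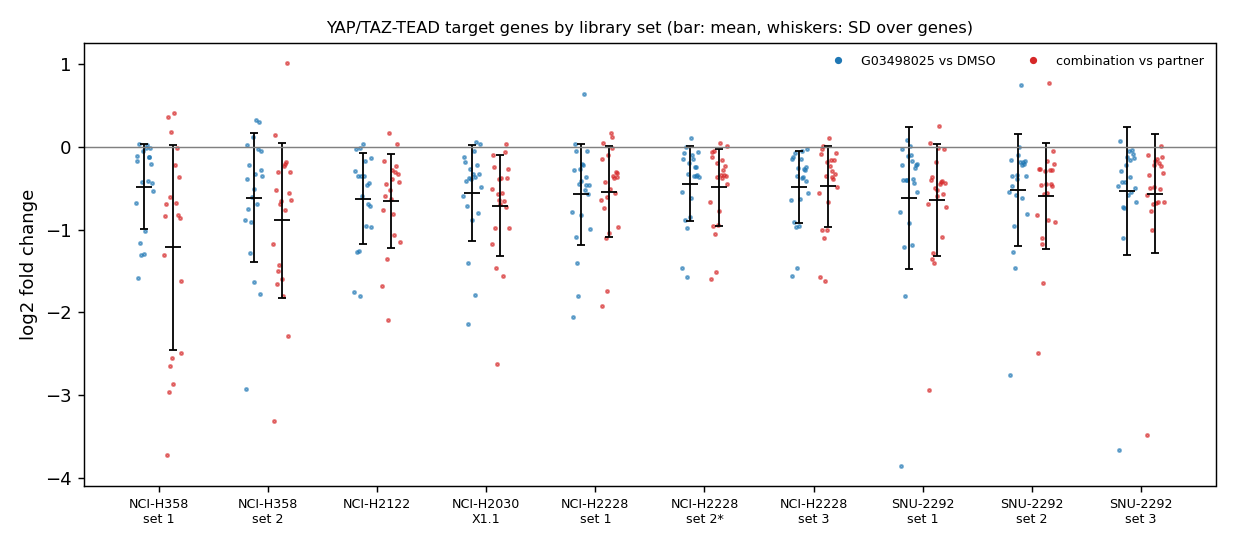
Log2 fold change of each YAP/TAZ-TEAD target gene (points) with the list mean and SD over genes, by library set, for G03498025 against DMSO and for the combination against the partner alone. Set 2* of NCI-H2228 leaves out the libraries labelled DMSO replicate 3 and G03498025 replicate 1; means for G03498025 run from -0.45 to -0.63.

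Beyond this list, G03498025 changed 472 genes in NCI-H358 (303 rose, 169 fell), 1576 in NCI-H2122 (587 and 989), 3617 in NCI-H2030 X1.1 (1882 and 1735), 2149 in NCI-H2228 (1230 and 919) and 2488 in SNU-2292 (1386 and 1102). In the 3 lines with several sets, differences in treatment effects between sets entered the spread of the fit. Libraries of a set share such differences but were counted as independent, so pooled p values there may be too low. Within sets the counts were 1572 and 5627 in NCI-H358, 3357, 3053 and 5571 in NCI-H2228 (set 2 without the 2 doubted libraries), and 1931, 2257 and 3894 in SNU-2292. The pooled NCI-H358 count was 204 with a replicate block, 311 without the low-count filter and 890 with DESeq2. That of NCI-H2228 was 3702 without the 2 doubted libraries, and the NCI-H2030 X1.1 count fell by over 1.5 times without DMSO replicate 3. For NCI-H358, NCI-H2228 and SNU-2292 the counts were 13, 397 and 259 without the set term and 3787, 4597 and 4785 with only the 2 groups. In NCI-H358 the largest rises were SLITRK6 (1.43), MMP1 (1.33) and NECTIN4 (1.31), and the largest falls LYPD5 (-1.61), DKK1 (-1.41) and EDN1 (-1.36). In NCI-H2122 S100A8 (1.64), CYP1B1 (1.32) and SERPINB3 (1.19) rose, and CHAC1 (-3.59), KRT4 (-2.32), SLC1A4 (-2.08) and DDIT3 (-1.82) fell. In NCI-H2030 X1.1 CYP1A1 (2.05) and KCNJ6 (1.30) rose, and LINC00707 (-2.73), THBS1 (-2.39), CCN2 (-2.14) and WNT7B (-2.10) fell. In SNU-2292 PTGS2 (1.93), GDF15 (1.78), MMP1 (1.66) and NRG1 (1.46) rose, and AOX1 (-2.19), CCBE1 (-1.98), ANXA3 (-1.93) and CPA4 (-1.73) fell. In NCI-H2228 the rule on named genes left only small changes, led by ARL15 (0.20) and MYO15B (-0.33), because the 2 doubted libraries made the groups overlap.

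Some genes moved alike in every library set. Of 13877 genes tested in all 10 sets (set 2 of NCI-H2228 without the 2 doubted libraries), 35 fell in every set and 7 rose in every set, against 4.72e-07 and 9.12e-08 if the calls of different sets were independent. Sets of 1 line are not independent of each other, so these expectations are likely too low. In the reported fits over whole lines, 14 of 14469 genes fell in all 5 lines and 4 rose. The genes listed next were chosen after their values were seen. The 7 that rose in every set were CYP1A1 (mean 1.96), CYP1B1 (1.24), BMF (0.84), GBP2 (0.66), TIPARP (0.54), NQO1 (0.34) and TMEM59 (0.32). Of these, only CYP1B1 also rose in all 5 fits over whole lines. Among the 35 that fell, AOX1 (-1.92), CPA4 (-1.52), DKK1 (-1.48), EDN1 (-1.44), ANXA3 (-1.40), CCN2 (-1.36) and CCN1 (-1.23) had the largest mean falls. CPA4 and EDN1 did not fall in all 5 fits over whole lines.

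Within the Hippo pathway list, WWC1 fell in all 5 lines, by 0.24 in NCI-H2122 to 0.77 in SNU-2292. VGLL1 was measured in 2 lines and fell in both (-3.77 in NCI-H358 and -4.45 in NCI-H2122). The list as a whole fell by camera only in NCI-H2122 (mean -0.33, 1 rose, 6 fell and 15 did not pass; adjusted p = 0.0016), a call lost with an estimated correlation (0.19).

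MAPK output genes did not follow a single course with G03498025. The 10-gene list fell in NCI-H2122 (mean -0.31, 6 fell, 4 did not pass, 7 fell adjusted over the list alone; adjusted p = 1.2e-07, held at 0.0438). It did not pass in the other 4 lines, with means of 0.04 in NCI-H358, -0.05 in NCI-H2030 X1.1, -0.05 in NCI-H2228 and 0.26 in SNU-2292. In sets 2 and 3 of SNU-2292 it rose, with means of 0.43 (7 rose, 2 fell) and 0.51 (8 rose, 1 fell), and both calls held with an estimated correlation.

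In the fits over whole lines, a call with G03498025 alone held with an estimated correlation in at most 1 line for each remaining list. More calls held within single sets. The G1/S call held in sets 1 and 2 of NCI-H358, set 2 of NCI-H2228 without the 2 doubted libraries, and sets 1 and 3 of SNU-2292. The epithelial call held in sets 1, 2 and 3 of SNU-2292, and the antigen presentation call in sets 1 and 3 of NCI-H2228. The G2/M call held in set 1 of NCI-H358 and set 3 of SNU-2292. The cholesterol synthesis call held in sets 1 and 3 of SNU-2292 and in set 2 of NCI-H2228 without the 2 doubted libraries. The values below are from whole lines. In NCI-H2122 the ATF4 stress list fell (mean -0.95, 13 of 16 fell, 13 fell adjusted over the list alone, held at 0.00813), as did the mesenchymal list (-0.52, 4 fell; 0.0179) and the receptor tyrosine kinase list (-0.30, 1 rose, 9 fell; 0.0186). In NCI-H358 the alveolar type 2 list was called up (0.60; 0 genes passed, 4 adjusted over the list alone; 0.0368). In SNU-2292 the NRF2 target list rose (0.36, 9 rose, 1 fell; 0.00986). Camera called 10 of 25 lists in NCI-H358, 13 of 24 in NCI-H2122, 10 of 22 in NCI-H2030 X1.1, 9 of 25 in NCI-H2228 and 12 of 25 in SNU-2292, and with an estimated correlation 2, 5, 1, 1 and 1 of these held. Calls lost included G2/M genes in NCI-H2030 X1.1 (mean -0.31, 17 fell; 0.20) and in NCI-H2122 (-0.24, 10 fell; 0.17), and in SNU-2292 cholesterol synthesis (-0.24, 12 fell; 0.063) and epithelial genes (-0.42, 9 fell; 0.063). The G1/S list was called down in SNU-2292 (-0.22, 0 genes passed), a call lost at 0.61. In NCI-H2228 antigen presentation rose (0.21, 10 rose, lost at 0.13), as did alveolar type 2 genes (0.44, 4 rose, lost at 0.098). The receptor tyrosine kinase list there was called down with a mean of -0.05 and a median of 0.01, a call also lost. Without the 2 doubted libraries the alveolar type 2 and receptor tyrosine kinase calls held. SRF/MRTF cytoskeletal genes fell in NCI-H2030 X1.1 (-0.32, 8 fell, lost at 0.20).

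With G03498025, gastric and mucinous genes rose in NCI-H2122 (mean 0.30, 5 rose, lost at 0.090). Squamous genes were called up in NCI-H358 (0.64, 1 rose, lost at 0.16). AP-1 genes were called down in NCI-H358 (-0.19, 0 passed, lost at 0.16), as CDK inhibitors and p53 targets were called up (0.29, 1 rose, lost at 0.060), interferon-stimulated genes up (0.29, 1 rose, lost at 0.41) and glycolysis genes up (0.21, 2 rose, lost at 0.41). Fibroblast markers were called up in NCI-H2228 (0.37, 3 rose, lost at 0.25), and leukocyte and endothelial markers were called in none of the 4 lines in which at least 3 were measured. Mitochondrial mRNAs rose in NCI-H2030 X1.1 (0.36, 10 rose, lost at 0.38) and in NCI-H2122 (0.25, 6 rose, lost at 0.18). Ribosomal protein genes were called down in NCI-H2228 (-0.12, 6 fell, lost at 0.15). The BCL2 family list was called in no line, although BCL2L1 fell in each of the 10 sets.

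The size of the G03498025 effect differed between lines for 5114 of 23284 genes (edgeR F test of equal effects). The difference covered ANKRD1 (adjusted p = 2.3e-05), AMOTL2 (8.2e-08), CCN2 (0.00367), CHAC1 (8.1e-16) and DUSP6 (1.8e-04), but not CCN1 (0.165) or MKI67 (0.605). The sample titles carry an NGS code that, among the lines, only NCI-H2122 and NCI-H2030 X1.1 share. Differences between other lines cannot be told apart from differences between these codes.

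Comparing each partner with DMSO asks what the second inhibitor changed. G03427947 lowered MAPK output genes. DUSP6, ETV4, ETV5 and SPRY4 fell steeply in NCI-H358, NCI-H2122 and NCI-H2030 X1.1. The change of DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271) was -5.87 ± 0.56 (SE, adjusted p = 2.5e-08), -3.52 ± 0.07 (6.4e-15) and -3.67 ± 0.16 (1.9e-12) in these lines. ETV4 (ENSG00000175832, chromosome 17, 43527844 to 43579620) changed by -5.02, -4.83 and -5.05, and SPRY4 (ENSG00000187678, chromosome 5, 142310427 to 142326455) by -4.52, -4.37 and -2.61. The list mean was -3.13 in NCI-H358 (1 rose, 9 fell; adjusted p = 6.1e-07), -2.20 in NCI-H2122 (1 rose, 9 fell; 1.9e-90) and -2.19 in NCI-H2030 X1.1 (9 fell, 1 did not pass; 5.8e-56), with the same counts adjusted over the list alone. With an estimated correlation the NCI-H2122 (3.6e-05) and NCI-H2030 X1.1 (1.3e-04) calls held and the NCI-H358 call was lost (0.144), although both NCI-H358 sets passed separately, with means of -4.50 and -2.17.

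G02925614 lowered MAPK output in set 1 of its lines and hardly in the later sets. In set 1 the list mean was -0.71 in NCI-H2228 (1 rose, 9 fell) and -1.36 in SNU-2292 (1 rose, 8 fell), and both calls held. In sets 2 and 3 it lay between -0.06 and 0.02 with 0 genes passing. DUSP6 went from 80.57 ± 2.00 CPM in DMSO to 24.81 ± 1.61 with G02925614 in NCI-H2228 set 1 (n = 3 each), and from 34.41 ± 0.69 to 37.22 ± 0.25 in set 3. Over all sets the list mean was -0.23 in NCI-H2228 (1 rose, 2 fell, 7 did not pass; 1 rose and 6 fell adjusted over the list alone; 0.0241) and -0.47 in SNU-2292 (5 fell, 5 did not pass; 1 rose and 8 fell adjusted over the list alone; 1.2e-04). Both calls were lost with an estimated correlation (0.482 and 0.522).

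**Figure D3:**
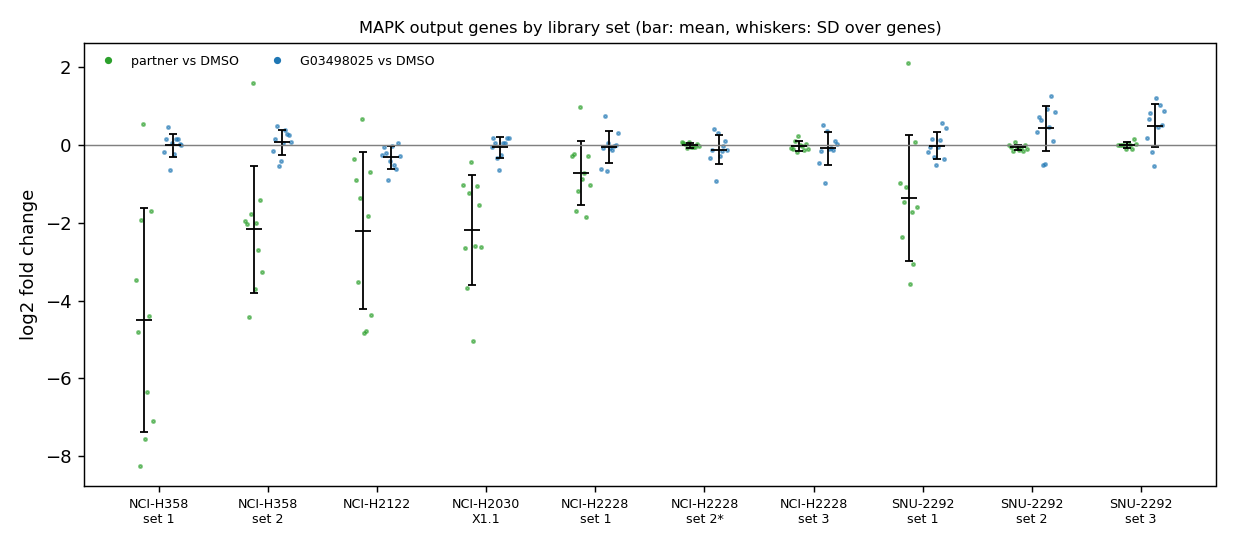
Log2 fold change of each MAPK output gene (points) with the list mean and SD over genes, by library set, for the partner against DMSO and for G03498025 against DMSO. Set 2* of NCI-H2228 leaves out 2 doubted libraries; partner means run from -4.50 in NCI-H358 set 1 to 0.00 in SNU-2292 set 3.

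G03427947 changed 9918 genes in NCI-H358 (5117 rose, 4801 fell), 5045 in NCI-H2122 (2404 and 2641) and 8119 in NCI-H2030 X1.1 (4073 and 4046). G02925614 changed 2750 in NCI-H2228 (1670 and 1080) and 438 in SNU-2292 (229 and 209). By set, G02925614 changed 11271, 0 and 165 genes in NCI-H2228, where 0 also resulted without the 2 doubted libraries, and 10359, 0 and 23 in SNU-2292. The pooled NCI-H2228 count was 666 with a replicate block, 1408 without the low-count filter, 1016 with only the 2 groups, 86 without the set term and 3818 with DESeq2, and that of NCI-H358 4039 without the set term. The pooled SNU-2292 count, from which CRISPLD2 and ITGA2 below are drawn, was 1, 121, 0, 0 and 1948 in these fits. Without the 2 doubted libraries NCI-H2228 gave 4899. Averaging treatment-by-set means gave larger counts in NCI-H2228 and SNU-2292, printed with the processing alternatives. In NCI-H358 G03427947 raised CNN1 (4.83) and TP53INP1 (4.44) and lowered MYEOV (-5.59) and AREG (-4.19). In NCI-H2122 it raised KRT4 (2.95), CCDC80 (2.10) and BMF (1.93) and lowered CHAC1 (-5.02). In NCI-H2030 X1.1 it raised C1S (2.50), TIMP3 (2.50) and CXCL12 (2.38) and lowered CXCL8 (-4.53) and CCL20 (-3.61). In NCI-H2228 PSG5 (1.46) and ANKRD1 (0.97) rose and TNC (-1.23) fell with G02925614, and in SNU-2292 CRISPLD2 (0.79) rose and ITGA2 (-0.75) fell.

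Proliferation genes fell with the partner in some lines and not in others. All 22 G2/M genes fell in NCI-H2030 X1.1 (mean -1.16, held at 0.0177) and in NCI-H358 (-1.95, lost at 0.61), where the sets gave -3.61 and -0.24. In NCI-H2122 the list rose instead (0.18, 10 rose, lost at 0.42). In NCI-H2228 the mean was -0.53 (1 fell, 14 fell adjusted over the list alone) and in SNU-2292 -0.54 (0 fell, 22 fell adjusted over the list alone), both lost (0.48 and 0.52). Set 1 of these lines gave -1.53 and -1.52 with 22 genes fallen in each, and the later sets lay between -0.06 and 0.00. The mean of the G1/S genes was -0.80 in NCI-H2030 X1.1 (22 fell, held at 0.00392), -1.53 in NCI-H358 (22 fell, lost at 0.57), 0.17 in NCI-H2122 (10 rose, 1 fell, lost at 0.33), -0.49 in NCI-H2228 (3 fell, lost at 0.48) and -0.39 in SNU-2292 (0 fell, lost at 0.52). In set 1 of NCI-H358, NCI-H2228 and SNU-2292 fitted alone, the G2/M and G1/S calls both held. In the later sets of these lines neither held.

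YAP/TAZ-TEAD targets moved both ways under the partner. CCN1 rose by 1.26 in NCI-H358, 0.99 in NCI-H2122, 0.43 in NCI-H2030 X1.1 and 0.60 in NCI-H2228, and the 0.80 of SNU-2292 did not pass (0.0593). These CCN1 values differed by set, with 2.05 and 0.23 in NCI-H358, 1.25, 0.39 (0.14 without the 2 doubted libraries) and 0.12 in NCI-H2228, and 1.92, 0.20 and 0.16 in SNU-2292. CCN2 fell in NCI-H358 (-0.79) and NCI-H2030 X1.1 (-1.01) and rose in NCI-H2122 (0.90) and SNU-2292 (0.66). The list was called only in SNU-2292 (mean 0.36, 2 rose, 20 did not pass, 13 rose and 2 fell adjusted over the list alone; 1.1e-05, lost at 0.52), where set 1 gave 0.94 (18 rose, 2 fell). Of the other lists, those that held over whole lines with an estimated correlation were in NCI-H2122 the ATF4 list (-1.20, 13 fell; 0.0262), gastric and mucinous genes (-0.96, 2 rose, 8 fell; 0.00534) and cholesterol synthesis (0.29, 14 rose, 2 fell; 0.0494), and in NCI-H2030 X1.1 the NRF2 list (0.45, 11 rose, 1 fell; 0.0371). Squamous genes in NCI-H2122 had a mean of -0.29, a median of 0.14 and a call down (lost at 0.20). Glycolysis genes were called down in all 5 lines, from -0.95 (15 fell) in NCI-H358 to -0.23 (0 passed) in SNU-2292, and no call over a whole line held. Within single sets the glycolysis call held in set 1 of NCI-H358, NCI-H2228 and SNU-2292, and in no later set.

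The G03427947 effect differed between its 3 lines for 7216 of 20957 genes, DUSP6 (adjusted p = 0.00803) and CCN2 (2.0e-06) included and ETV4 (0.95) not. The G02925614 effect differed between NCI-H2228 and SNU-2292 for 75 of 19695 genes. With set 1 of each line alone the 3 tests of differences between lines called 3868, 11947 and 5882 genes.

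Comparing the combination with the partner alone asks what G03498025 adds once the second inhibitor is present. Here too it lowered YAP/TAZ-TEAD targets in every line. CCN1 fell by 2.35 ± 0.23 (SE, adjusted p = 3.4e-07) in NCI-H358, by 1.36 in NCI-H2122, by 1.47 in NCI-H2030 X1.1, by 1.09 in NCI-H2228 and by 1.15 in SNU-2292. CCN2 fell by 2.02, 2.09, 2.63, 1.66 and 1.25. AXL, AMOTL2, F3, EPHA2 and WWC1 fell in all 5 lines as well. The list mean was -1.08 in NCI-H358 (14 fell, 7 did not pass; 15 adjusted over the list alone), -0.65 in NCI-H2122 (1 rose, 17 fell; 18 fell adjusted over the list alone) and -0.71 in NCI-H2030 X1.1 (17 fell; 18 adjusted over the list alone). It was -0.52 in NCI-H2228 (16 fell; 17 adjusted over the list alone) and -0.58 in SNU-2292 (14 fell; 16 adjusted over the list alone). Adjusted p values with an estimated correlation were 8.1e-05, 0.0236 and 2.9e-04 in the first 3 lines, and the calls of NCI-H2228 (0.0553) and SNU-2292 (0.065) were lost. Fitted alone, sets 1 and 3 of NCI-H2228 and sets 1, 2 and 3 of SNU-2292 held the call. Set 2 of NCI-H2228 held it without the 2 doubted libraries but not as labelled. The NCI-H2228 fit over all sets also held it without these libraries.

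In this comparison 2285 genes changed in NCI-H358 (1278 rose, 1007 fell), 6409 in NCI-H2122 (3258 and 3151), 2563 in NCI-H2030 X1.1 (1056 and 1507), 5330 in NCI-H2228 (2838 and 2492) and 3027 in SNU-2292 (1668 and 1359). In NCI-H358, NCI-H2228 and SNU-2292 the counts were 144, 2220 and 391 without the set term and 5905, 8683 and 5842 with only the 2 groups, and NCI-H358 gave 1452 with a replicate block. CYP1A1 was the largest named rise in NCI-H358 (2.28), NCI-H2030 X1.1 (1.51) and NCI-H2228 (2.60). In NCI-H2122 S100A8 (2.23) and SERPINB3 (1.79) rose and EFEMP1 (-1.99) and THBS1 (-1.83) fell. CNN1 (-3.23) and SERPINE1 (-3.01) fell in NCI-H358, TIMP3 (-3.35) and WNT7B (-3.06) in NCI-H2030 X1.1, KRT4 (-1.98) and ANKRD1 (-1.75) in NCI-H2228, and ANKRD1 (-2.89) and ANXA3 (-2.06) in SNU-2292, where MMP1 (2.04) and PTGS2 (2.03) rose. Over the 10 sets, 71 genes fell and 13 rose in every set.

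With G03498025 added to the partner, the mean of the G2/M list was below 0 in each set, and its size differed by set. All 22 G2/M genes fell in NCI-H2030 X1.1 (mean -0.64, held at 0.0221), and 18 fell in NCI-H2122 (-0.43, lost at 0.13). In the lines with several sets the additive fit passed few of them (0 in NCI-H358, 1 in NCI-H2228, 0 in SNU-2292) and the calls were lost (0.55, 0.54 and 0.55), but within sets 22 fell in both NCI-H358 sets (-1.52 and -0.69), 22 in set 1 of NCI-H2228 (-1.10) and 22 in set 1 of SNU-2292 (-0.89), and these 4 calls held. In the later sets 18 fell in NCI-H2228 set 2 (-0.28, lost at 0.35), 21 in its set 3 (-0.32, held at 0.0138), 3 in SNU-2292 set 2 (-0.10, lost at 0.45) and 13 in its set 3 (-0.21, lost at 0.075). Of the other lists, those that held over whole lines included the G1/S list, called down in NCI-H2030 X1.1. SRF/MRTF cytoskeletal genes held in NCI-H358 (-0.58, 9 fell, 0.0331) and NCI-H2030 X1.1 (-0.74, 14 fell, 0.0138). Mesenchymal genes held in NCI-H2030 X1.1 (-0.57, 4 rose, 6 fell, 0.0221), and receptor tyrosine kinases in NCI-H358 (-0.42, 0.032) and NCI-H2030 X1.1 (-0.22, 0.025). NRF2 targets rose in NCI-H358 (0.42, 4 rose; 0.0121), NCI-H2122 (0.26, 12 rose, 1 fell; 0.0336) and SNU-2292 (0.36, 8 rose, 1 fell; 0.00844). Hippo genes fell in NCI-H358 (-0.35, 1 rose, 9 fell; 0.0029), alveolar type 2 genes rose in NCI-H2228 (0.67, 8 rose; 0.0336), and epithelial genes (-0.60, 10 fell; 0.0258) and cholesterol synthesis (-0.31, 15 fell; 0.0258) fell in SNU-2292. Squamous genes in NCI-H2122 had a mean of 0.20, a median of -0.03 and a call up that was lost (0.33). Within single sets, MAPK output genes were called up in sets 1 and 3 of SNU-2292, and both calls held.

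Comparing the combination with G03498025 alone asks what the partner adds. In the 3 lines given G03427947, MAPK output genes fell, with means of -3.15 in NCI-H358 (1 rose, 9 fell, lost at 0.10), -1.75 in NCI-H2122 (1 rose, 9 fell, held at 3.5e-04) and -1.71 in NCI-H2030 X1.1 (1 rose, 9 fell, held at 2.9e-05). In NCI-H2228 the mean was -0.27 (1 rose, 7 fell, lost at 0.65) and in SNU-2292 -0.30 (2 fell, lost at 0.37). By set it was -0.76 (1 rose, 9 fell, held at 0.0384), -0.01 (0 passed; 0.03 without the 2 doubted libraries) and -0.01 (1 rose, 2 fell) in NCI-H2228, and -0.79 (2 rose, 8 fell, held at 0.00475), -0.15 (0 passed, lost at 0.31) and -0.03 (0 passed) in SNU-2292. The counts of changed genes were 10893 in NCI-H358 (5700 rose, 5193 fell), 7883 in NCI-H2122 (3906 and 3977), 7698 in NCI-H2030 X1.1 (3786 and 3912), 7574 in NCI-H2228 (3613 and 3961) and 1120 in SNU-2292 (604 and 516). By set they were 11838, 10 and 1041 in NCI-H2228 (174 in set 2 without the 2 doubted libraries) and 11085, 7 and 18 in SNU-2292. The pooled SNU-2292 count was 70 with a replicate block, 318 without the low-count filter, 0 with edgeR on only the 2 groups or without the set term, and 2849 with DESeq2, and without the set term NCI-H358 gave 5295 and NCI-H2228 3582. All 22 G2/M genes fell in NCI-H358 (-2.60, lost at 0.49), NCI-H2030 X1.1 (-1.49, held at 0.00456) and NCI-H2228 (-0.85, lost at 0.44). The sets of NCI-H358 gave -4.98 and -0.69. Those of NCI-H2228 gave -2.46 (22 fell), -0.25 (0 passed; -0.18 with 4 fallen without the 2 doubted libraries) and -0.15 (16 fell). The largest named changes were SAMD11 (4.34) and FOSL1 (-4.66) in NCI-H358, KRT4 (4.07) and ETV4 (-4.18) in NCI-H2122, CXCL12 (2.29) and CXCL8 (-4.73) in NCI-H2030 X1.1, PLA1A (1.17) and E2F8 (-1.01) in NCI-H2228, and CCN1 (0.82) and ESPL1 (-0.77) in SNU-2292.

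The interaction asks whether the combination departs from the sum of the single effects on the log2 scale. It differed by line. In NCI-H2122, the stress genes CHAC1 (3.29), SLC1A4 (2.17) and DDIT3 (1.77), which fell with G03498025 alone, lay above the sum, as did EGR1 (1.95). CHAC1 and the ATF4 list also fell with G03427947 alone, so lying above the sum does not mean that they rose in the combination. The ATF4 list there had a mean of 0.92 (11 rose, 12 adjusted over the list alone; 6.1e-21, lost at 0.070). In NCI-H358, HBEGF (-1.68), NRG1 (-1.68) and SEMA7A (-1.41) fell below the sum and RDH10 (1.45) rose above it. In NCI-H2030 X1.1 ETV5 (0.95) and ETV4 (0.88) lay above the sum and LRATD2 (-1.28) and SCARA3 (-1.29) below it. It covered 71 genes in NCI-H358 (13 rose, 58 fell), 2213 in NCI-H2122 (1160 and 1053) and 333 in NCI-H2030 X1.1 (72 and 261). Of 25 splits of the samples, 3 called as many genes in NCI-H2122 (highest other 5964) and 3 in NCI-H2030 X1.1 (highest other 607), the others of these by exchanging G03498025 labels unevenly between partner levels. With 1 library left out, the lowest count was 1135 in NCI-H2122 (without combination replicate 1) and 181 in NCI-H2030 X1.1 (without DMSO replicate 2). In NCI-H2228 and SNU-2292 edgeR called 0 genes, with 957 and 557 at an unadjusted p under 0.05, while DESeq2 called 1 and 0. Set 1 of these lines called 980 and 1377, and the sets of NCI-H358 called 1789 (606 rose, 1183 fell) and 2244 (1107 and 1137). The pooled NCI-H358 count was 30 with a replicate block, 0 with edgeR without the set term and 173 with DESeq2, and that of NCI-H2030 X1.1 was 737 with a replicate block, 672 without the low-count filter and 560 with DESeq2.

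MAPK output genes lay above the sum in NCI-H2122 (mean 0.45, 6 rose, lost at 0.13) and NCI-H2030 X1.1 (0.48, 3 rose, lost at 0.098). In set 1 of SNU-2292 fitted alone they were also called above the sum, and that call held. Among the other fixed lists, YAP/TAZ-TEAD targets were called below the sum in NCI-H358 (mean -0.49, 0 genes passed, 8 fell adjusted over the list alone; 5.6e-10, held at 0.0308), with -0.73 and -0.28 in its sets. NCI-H2030 X1.1 gave -0.15 (4 fell, lost at 0.15) and the other 3 lines were not called. In NCI-H358 the Hippo (-0.12), receptor tyrosine kinase (-0.32) and SRF/MRTF (-0.46) lists also held below the sum and the NRF2 list (0.25) above it. In SNU-2292 the ATF4 list (-0.20, 0 passed) held at 0.0342. G2/M genes lay below the sum in some sets, with 22 of 22 fallen in both NCI-H358 sets (-1.37 and -0.45), in set 1 of NCI-H2228 (-0.93) and in set 1 of SNU-2292 (-0.67). In the later sets 0 genes passed, with means of -0.26 (-0.12 without the 2 doubted libraries) and -0.13 in NCI-H2228 and 0.07 and 0.05 in SNU-2292. Interferon-stimulated genes fell in set 1 of SNU-2292 when G03498025 joined the partner (-1.44, 21 of 22 fell; interaction -1.60). In sets 2 and 3 the same comparison gave 0.13 (10 rose) and 0.17 (9 rose).

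**Figure D4:**
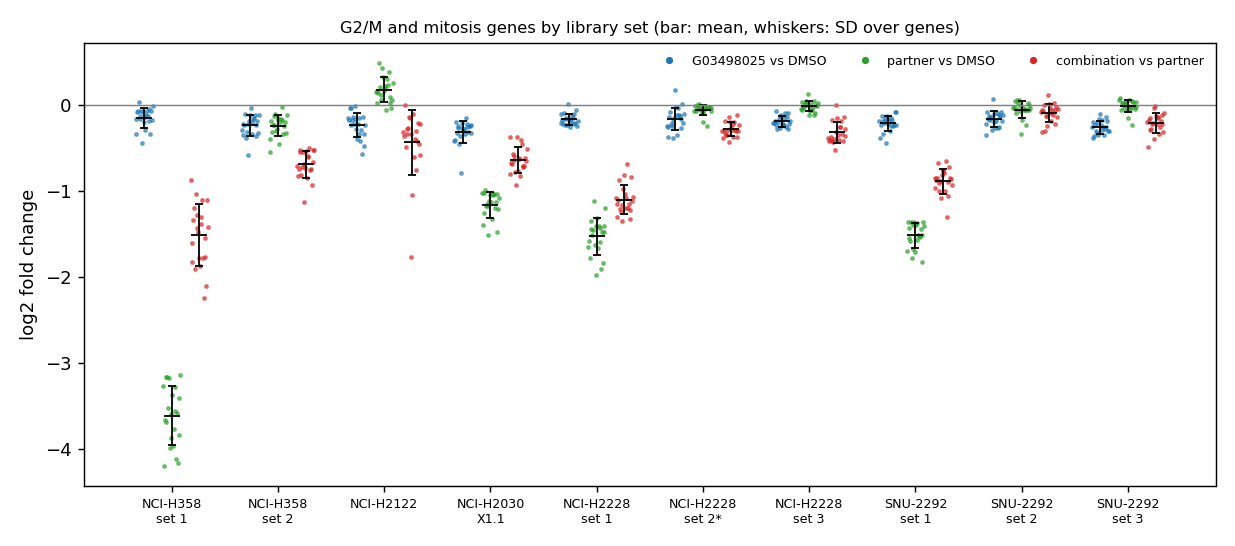
Log2 fold change of each G2/M gene (points) with the list mean and SD over genes, by library set. Adding G03498025 to the partner gave means from -1.52 in NCI-H358 set 1 to -0.10 in SNU-2292 set 2; set 2* of NCI-H2228 leaves out 2 doubted libraries.

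The library sets of a line carry the same labels but did not give the same values. Treatment effects differed between sets for 12192 of 18523 genes in NCI-H358, 10530 in NCI-H2228 and 11009 in SNU-2292 (edgeR F test of treatment-by-set terms). Without the 2 doubted libraries, the G03498025 effect differed for 2216, 682 and 743 genes and the partner effect for 9589, 9473 and 8581. The DMSO libraries also differed between sets. Between DMSO libraries of a later set and of set 1, 12301 genes differed in NCI-H358, 7153 and 7675 in NCI-H2228, and 11804 and 11001 in SNU-2292. In SNU-2292, DUSP6 stood 2.78 and 2.43 log2 units lower in DMSO of sets 2 and 3 than of set 1. In NCI-H358, CCN1 stood 2.64 higher in DMSO of set 2. There the fibroblast marker list lay 4.15 above set 1 (9 of 10 genes higher) and the mesenchymal list 1.73 above it (14 of 16 higher), and the epithelial list had a mean of -1.27 (17 of 18 lower). Pearson's r between DMSO means of a later set and of set 1 was 0.849 in NCI-H358, 0.982 and 0.983 in NCI-H2228, and 0.913 and 0.934 in SNU-2292. The pooled effects in NCI-H358, NCI-H2228 and SNU-2292 average over these sets, and their p values do not measure the spread of effects between sets.

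The effect of G03498025 was estimated 2 times per set from separate libraries, alone against DMSO and in combination against the partner. Genes called in both outnumbered chance in each set. In NCI-H2228 set 3, 2070 genes fell in both against 495.8 for independent lists, 2171 rose in both against 513.9, and 4 moved in opposite directions. In NCI-H358 set 1, 458 fell in both against 102.3, 442 rose in both against 88.7, and 81 moved in opposite directions. Across genes, which are not independent replicates, Pearson's r between the 2 estimates ran from 0.255 to 0.629 over the 10 sets.

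In NCI-H2228 set 2, the library labelled DMSO replicate 3 and the library labelled G03498025 replicate 1 lay with the other treatment. On an axis running from 0 at the partner libraries to 1 at the combination libraries, the libraries labelled DMSO lay at 0.012, 0.027 and 0.799. Those labelled G03498025 lay at 0.022, 0.801 and 0.814. As labelled, this set called 0 genes for G03498025 against DMSO with edgeR, and without the 2 libraries it called 3053. The pooled values of NCI-H2228 keep the labels as given.

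**Figure D5:**
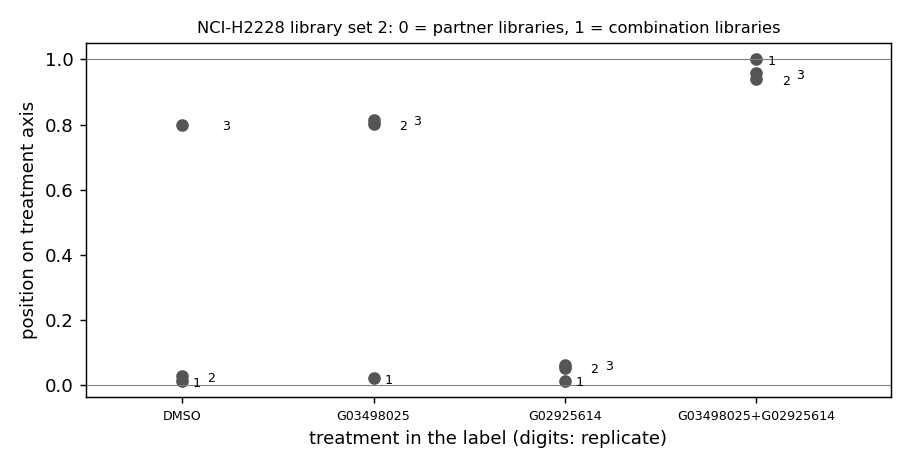
Position of each NCI-H2228 set 2 library (points, with replicate numbers) on an axis from 0, the mean of the partner libraries, to 1, the mean of the combination libraries, by the treatment in the label. The library labelled DMSO replicate 3 lies at 0.799 and the library labelled G03498025 replicate 1 at 0.022.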

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

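The comparison of other splits of the samples and the test of MAPK output in DMSO cells had their criteria written before their values were seen; the other tests here of the doubted libraries and of the library sets were chosen after the result was seen. The bound used for a mixture of lines in SNU-2292 replaced an earlier bound after the value was known.

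5 values lay far from the other libraries of their group by Dixon's test, among 72 tests of a group and a measure; chance gives about 1 in 20. The library of NCI-H2228 with G03498025, set 1, replicate 1, had a total of 87.3 M, 20185 genes with at least 10 counts and a MAPK output score of 6.87. The library of SNU-2292 with G03498025, set 2, replicate 2, had a total of 48.6 M and 19744 such genes.

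Several tests of differences passed. Treatment effects differed between library sets for 12192 genes in NCI-H358, 10530 in NCI-H2228 and 11009 in SNU-2292. The interaction test called 71 genes in NCI-H358, 2213 in NCI-H2122 and 333 in NCI-H2030 X1.1. In each of the last 2 lines 3 of 25 splits of the samples called as many, but apart from the labelled one these exchanged G03498025 labels unevenly between partner levels, which turns the effect of G03498025 into interaction, so this count does not decide about chance. With 1 library left out the lowest counts were 1135 without combination replicate 1 of NCI-H2122 and 181 without DMSO replicate 2 of NCI-H2030 X1.1. Effects differed between cell lines for 5114 genes with G03498025, 7216 with G03427947 and 75 with G02925614.

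In NCI-H2228 set 2, the library labelled DMSO replicate 3 and the library labelled G03498025 replicate 1 lie with the other treatment, and no biological explanation was tested. A mixture of both treatments in each is argued against by the position of the library labelled DMSO replicate 3, at 0.799, among the libraries labelled G03498025. Low depth of both is argued against by the total of 39.1 M of the first library, inside the range of the set; the second, at 32.0 M, had the lowest total of the set. Exchanged labels remain a candidate explanation, since the split that exchanges the 2 labels called 3288 genes where the labelled split called 0. Nothing outside the counts was available to test this.

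Library sets of 1 line with the same labels gave different partner effects, and the labels name no difference between the sets. Libraries of another line of this series are argued against by the correlation with the line's own set 1, which exceeded that with any other line by at least 0.12, which says nothing about a line from outside the series. Noisier later sets are argued against by 3894 genes called for G03498025 in set 3 of SNU-2292. Cells of another line of the series mixed in, as the source of genes absent from set 1, are argued against in SNU-2292 by 4 such genes under 1% of the other lines' lowest level in both later sets, where 9 and 6 exceeded 10% (an earlier bound asked for at least 5 under 1%), and in NCI-H358 by 12 under 1% where 10 exceeded 10%; other cells were not tested. A missing partner compound is argued against in set 3 of NCI-H2228 by 1041 genes between the combination and G03498025. In its set 2 that count was 10 (174 without the 2 doubted libraries), and G02925614 against DMSO called 0 genes. The explanation cannot be told apart for that set. Nor can it in SNU-2292, where the count between the combination and G03498025 was at most 18 in the later sets.

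Cells whose MAPK output was already low could show a smaller partner effect. In SNU-2292 the MAPK output list lay lower in DMSO of a later set than of set 1 by -1.61, so this may account for part of the difference there. In NCI-H2228 the mean shifts were 0.017 in set 2 and -0.016 in set 3. By the bound written beforehand these argue against a lower list mean in DMSO of its later sets. In set 2, 5 genes were higher and 4 lower, and DUSP6 stood lower in DMSO of sets 2 and 3 (-1.21 and -1.27). Lower output of single genes such as DUSP6 therefore cannot be told apart as an explanation. In NCI-H358 the shift was -0.55 and the explanation cannot be told apart from others, since the list still fell by 2.17 with G03427947 in set 2. Why the DMSO cells differ was not tested.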

How the results depend on the processing

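The alternatives were written before the data were examined, except the fits without 2 libraries of NCI-H2228 set 2 and the average of treatment-by-set means, which were chosen after seeing the data. Unless stated, the cause was not tested. Of all counts, 197 stayed within 1.5 times the reported value and 94 moved. List results were counted only for YAP/TAZ-TEAD targets with G03498025 and with the combination against the partner, and for MAPK output with the partner. Of these, 146 kept their side, 10 weakened and 3 reversed. Of the named genes, 3813 kept their side, 397 weakened and 4 reversed.

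DESeq2 size factors moved no count past 1.5 times. The DESeq2 Wald test called 890 genes for G03498025 in NCI-H358 (reported 472) and 173 for its interaction (71), 560 for the interaction in NCI-H2030 X1.1 (333), and in SNU-2292 1948 for G02925614 (438) and 2849 for the combination against G03498025 (1120). For the interactions with 0 genes in edgeR it called 1 in NCI-H2228 and 0 in SNU-2292, where 957 and 557 genes had an unadjusted p under 0.05. Without the low-count filter, counts were 311 for G03498025 in NCI-H358, 672 for the NCI-H2030 X1.1 interaction, 1408 for G02925614 in NCI-H2228, and in SNU-2292 121 for G02925614 and 318 for the combination against G03498025.

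The labels do not say that a replicate number marks a shared culture or day, and not every pair of libraries with the same number deviated together: 6 to 12 of 18 pairs per set had a correlation over 0.1. The mean correlation with the same number and with another number was 0.1795 and -0.0899 in NCI-H2030 X1.1, 0.1951 and -0.1021 in SNU-2292 set 1, and 0.1567 and -0.0764 in SNU-2292 set 3, so a shared source of some libraries is not ruled out there. In the other 7 sets the same-number mean ran from -0.0566 to 0.0442. With a replicate block, counts were 204 for G03498025 in NCI-H358, 1452 for the combination against G03427947 and 30 for the interaction there. They were 666 for G02925614 in NCI-H2228, 737 for the NCI-H2030 X1.1 interaction, and in SNU-2292 1 for G02925614 and 70 for the combination against G03498025. Among the contrasts within lines, the replicate block changed no other count by over 1.5 times. It changed none of the 15 YAP/TAZ-TEAD and MAPK output list calls that were rerun.

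Fitting only the 2 groups compared gave for G03498025 against DMSO 3787 genes in NCI-H358, 4597 in NCI-H2228 and 4785 in SNU-2292, and for the combination against the partner 5905, 8683 and 5842. For G02925614 it gave 1016 in NCI-H2228 and, with edgeR, 0 in SNU-2292, where the combination against G03498025 also gave 0. Without the library set term the counts for G03498025 were 13 in NCI-H358, 397 in NCI-H2228 and 259 in SNU-2292. For the partner they were 4039, 86 and 0, for the combination against the partner 144, 2220 and 391, and for the combination against G03498025 5295, 3582 and 0; the NCI-H358 interaction gave 0.

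Each library set alone gave other counts. In NCI-H358, G03498025 changed 1572 and 5627 genes in sets 1 and 2, the combination against the partner 4376 and 8376, and the interaction 1789 and 2244. In NCI-H2228, G03498025 changed 3357, 0 and 5571 in sets 1 to 3, and G02925614 11271, 0 and 165. The combination gave 11838, 10 and 1041 against G03498025, and 3185 against the partner in set 2 (5632 without the 2 doubted libraries). The interaction in set 1 gave 980. In SNU-2292, G03498025 changed 3894 in set 3, G02925614 10359, 0 and 23, the combination against G03498025 11085, 7 and 18, the combination against the partner 4973 in set 1, and the interaction 1377 in set 1. With set 1 of each line alone, effects of G03427947 differed between lines for 11947 genes (7216) and of G02925614 for 5882 (75).

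Averaging treatment-by-set means, chosen after seeing the data, gave for G03498025 5171 genes in NCI-H358, 5892 in NCI-H2228 and 5966 in SNU-2292, and for the combination against the partner 7901, 8948 and 6490. For G02925614 it gave 8085 in NCI-H2228 and 7139 in SNU-2292, where the combination against G03498025 gave 7559. The interactions gave 2315, 830 and 465. Here differences between sets no longer enter the spread. Leaving out the library labelled DMSO replicate 3 and the library labelled G03498025 replicate 1 gave 3702 genes for G03498025 in NCI-H2228 and 4899 for G02925614, and in set 2 alone 0 for G02925614 and 174 for the combination against G03498025.

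In the lines with 1 set each library was left out in turn. Counts in NCI-H2122 ran from 1104 to 1271 for G03498025, 4060 to 5097 for G03427947, 4722 to 6623 for the combination against G03427947, 6271 to 7263 against G03498025 and 1135 to 2718 for the interaction. The last fell to 1423 without G03498025 replicate 1, 1248 without G03498025 replicate 2 and 1135 without combination replicate 1. In NCI-H2030 X1.1 they ran from 2301 to 3364, 6973 to 7381, 1879 to 2420, 6675 to 7571 and 181 to 458 in the same order. Without DMSO replicate 3 the count for G03498025 was 2301. The interaction count was 181 without DMSO replicate 2, 196 without DMSO replicate 3, 198 without G03498025 replicate 2, and 202, 188 and 217 without G03427947 replicates 1, 2 and 3. The YAP/TAZ-TEAD and MAPK output list results, the only ones rerun, kept their side in these lines. YAP/TAZ-TEAD means for G03498025 ran from -0.64 to -0.62 in NCI-H2122 and -0.59 to -0.54 in NCI-H2030 X1.1.

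Among the list results counted here, an estimated correlation ended the YAP/TAZ-TEAD calls of SNU-2292 for G03498025 (mean -0.53, camera adjusted p 0.0799) and for the combination against the partner (-0.58, 0.065). It ended that of NCI-H2228 for the latter (-0.52, 0.0553). These YAP/TAZ-TEAD calls held in each set fitted alone, NCI-H2228 set 2 taken without the 2 doubted libraries. The estimated correlation also ended the MAPK output calls for the partner in NCI-H358 (-3.13, 0.144), NCI-H2228 (-0.23, 0.482) and SNU-2292 (-0.47, 0.522). In NCI-H2228 that list was not called with fry (-0.23, 0.0527), without the set term (-0.18) or in set 3 (-0.021), and turned positive in set 2 (0.022, and 0.0039 without the 2 libraries). In SNU-2292 it was -0.059 in set 2 and 0.0045 in set 3. Genes that changed sign were SPRY4 (0.034) and ETV4 (0.065) for G02925614 in SNU-2292 set 3, EPHA4 (-0.013) for G02925614 in NCI-H2228 set 2, and CCDC80 (0.0052) for the combination against the partner in NCI-H2228 set 3.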

Other observations

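The tests of the rise of CYP1A1 and 3 other genes in this part were chosen after the result was seen; the splits of the samples were planned.

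CYP1A1, CYP1B1, TIPARP and NQO1, chosen after their values were seen, rose with G03498025 in every library set, NCI-H2228 set 2 taken without the 2 doubted libraries. Reads of CYP1A2 counted for CYP1A1 are argued against as the source of its rise, since the level of CYP1A2 with G03498025 plus 2 SD was at most 8.14% of the rise of CYP1A1 over the 10 sets. An NRF2 response as the only cause cannot be told apart: the NRF2 target list had a mean of -0.026 in NCI-H2228 set 3 (3 rose, 5 fell), a criterion set after the value was seen, and it was called up in 7 of 10 sets, where an earlier criterion asked for fewer than 5. Transcription through the aryl hydrocarbon receptor may be involved: 48.6% of the values of the other 5 members of a list of its targets rose, and AHRR, 1 of these, rose in 8 of 10 sets, which leaves it open. Whether the compound or the inhibition of its target acts here cannot be told apart in this design.

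Other splits of the same samples were counted to see whether chance could give as many calls, 25 splits per result unless stated. In NCI-H358, 1 of 25 splits, the labelled one, gave as many genes for each contrast. This is the lowest share that 25 splits can give. Splits with mixed labels carry the treatment effect in their spread, so this count alone does not exclude chance. The labelled split called 472 and the highest other 47 for G03498025 against DMSO. The pairs were 9918 and 7214 for the partner, 2285 and 200 for the combination against the partner, 10893 and 90 for the combination against G03498025, and 71 and 4 for the interaction.

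In NCI-H2228 the labelled split was again the only 1 of 25 splits with as many genes for 4 contrasts. The labelled and highest other counts were 2149 and 2, 2750 and 45, 5330 and 1, and 7574 and 3830. In SNU-2292 they were 2488 and 1077, 438 and 11, 3027 and 1257, and 1120 and 3, each reached by 1 of 25 splits. For the interaction in both lines every split, 25 of 25, called 0 genes with edgeR, as the labels did, with 957 and 557 genes at an unadjusted p under 0.05.

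In NCI-H2122 and NCI-H2030 X1.1 the 10 splits of 3 against 3 libraries are too few for a share under 0.05. The labelled splits called 1576, 5045, 6409 and 7883 genes in NCI-H2122 and 3617, 8119, 2563 and 7698 in NCI-H2030 X1.1, and the highest other split called 0 each time. For the interaction, 3 of 25 splits gave as many genes in each line, so chance cannot be excluded by this count, which decides little. The labelled split called 2213 and the highest other 5964 in NCI-H2122, against 333 and 607 in NCI-H2030 X1.1. The splits with more genes than the labelled one point to a structure of the samples. Those in NCI-H2122 kept 0 and 1 of 3 G03498025 labels without the partner and 3 with it, and those in NCI-H2030 X1.1 kept 0 and 2, or 1 and 3, which turns the effect of G03498025 into interaction.

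For the differences between sets, 1 of 25 splits gave as many genes in each line. The labelled and highest other counts were 12192 and 607 in NCI-H358, 10530 and 4443 in NCI-H2228, and 11009 and 1806 in SNU-2292. For the differences between lines they were 5114 and 374, 7216 and 372, and 75 and 14, again with 1 of 25 splits each.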
